A study of Mus musculus with 30 samples.

How the data were processed

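The series holds 30 samples of total RNA from mouse retina, each hybridised as biotin-labelled cRNA to an array of its own. Per the labels and the series description, each line contributed several animals and each RNA sample went to a separate array, so the arrays of a group were taken as separate animals. The groups are R7N and R7E mice at 3 weeks (5 arrays each) and at 9 weeks (6 arrays each), and R6 and WT mice at 9 weeks (4 arrays each). R7E carries mutant ataxin-7, R7N normal ataxin-7 and R6 mutant huntingtin. The labels call 3 weeks the onset stage and 9 weeks the moderate stage. The R7 lines are 100% C57BL/6, and R6 and WT are 75% C57BL/6 and 25% CBA/J.

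The deposited value table gives 1 signal per probe set and array, which is an intensity on a linear scale. The submitters' processing notes name MAS5, with its version not stated. The authors' values were already scaled, since the mean without the highest and lowest 2% of values lay between 100.027 and 100.032 on each array. The median signal per array was 39.3 to 48.3. No scanner files were used here, so background correction and probe summaries are the authors' own. An array has no read depth, and the number of arrays per group limits the precision.

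The table holds 22690 probe sets, of which 64 are controls. Of the other 22626, the platform annotation names 1 gene for 20380, several for 691 and none for 1555, which gives 12393 distinct genes. No gene was named from a probe set with several genes. Values below 3.2, the 10th percentile of the table, were raised to 3.2 and log2 was taken, since MAS5 signals near background scatter widely on a log scale. Probe sets entered the tests if their mean over the 30 arrays lay above the 40th percentile, a signal of 26.9. This left 13575 probe sets, 12537 of them with 1 gene, for 8044 genes. Of the values tested, 0.0145% lay at the lower limit. Detection calls were not used here, so a signal near or under the filter's level is not shown to be above background, and a difference against it is no exact fold.

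A linear model with the 6 groups and the labelled sex of the animal was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3, with a mean-variance trend and 23 residual degrees of freedom. Sex was included because R7E holds more labelled females than R7N. These were 4 of 5 arrays against 1 of 5 at 3 weeks, and 3 of 6 against 1 of 6 at 9 weeks. There were 8 comparisons: R7E against R7N at each age, the change of that difference with age, R6 against WT, the difference of the R7E and R6 effects at 9 weeks, age within R7N and within R7E, and R7N against WT. Adjusted p values follow Benjamini and Hochberg over the probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. A probe set's p and adjusted p are from limma throughout. Differences are given on the log2 scale with ± 1 standard error, and signals as mean ± SD over the arrays of a group.

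Gene lists were fixed, with 1 probe set per gene, that of the highest mean. The 32 lists cover rod phototransduction, cone phototransduction, the photoreceptor outer segment and cilium, photoreceptor transcription factors, progenitor and differentiation inhibitor genes, cell cycle, Muller glia, reactive gliosis, microglia and macrophages, complement and antigen presentation, and interferon response. They also cover bipolar, amacrine, horizontal, ganglion and vascular cells, retinal pigment epithelium and melanocytes, lens, blood, skeletal muscle, photoreceptor and ribbon synapse, heat shock, endoplasmic reticulum stress, proteasome, apoptosis and immediate early genes. The others are the circadian clock, the SAGA complex and ataxin-7 partners, striatal signalling genes lowered in Huntington models, cholesterol synthesis, oxidative phosphorylation and glycolysis. Xist and Y-linked genes served only to check the sex labels. List shifts were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation and fry as alternatives, and were adjusted over the lists of a comparison. A list's call is that of camera at the preset correlation unless another test is named. Values of fry are given for some lists only, and it also called lists that camera did not. Members are also counted after adjustment over the list alone. Blood and skeletal muscle had no tested member and so no result. Lists can share a gene, as Stat3 stands in both the progenitor and gliosis lists.

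The choices above, the comparisons, the lists and the rule for named genes were made before the data were examined. By that rule the named genes are, in each of the R7E against R7N and R6 against WT comparisons, the 8 largest rises and 8 largest falls among called genes with 1 probe set per gene, and up to 3 called members of each list by adjusted p. In the other comparisons they are the 6 largest rises and falls. Mouse Atxn7 and Htt, the genes of the transgene proteins, were always included. The text names a subset of these genes, which was chosen after their values were seen, and a few genes outside the rule, which are named as such.

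Shared calls of R7E and R6 were compared with Fisher's exact test, two-sided, and with the number that independent calls would give. Those comparisons share no array. R6 against WT and R7N against WT share the WT arrays, and R7E against R7N and R7N against WT share the R7N arrays, so their chance deviations are shared. No overlap of calls was tested between them.

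The model and the list test were checked on simulated data in which 200 of 13575 probe sets were changed. At 3 weeks, 50.7% of 1.5-fold, 83.6% of 2-fold and 100.0% of 4-fold changes were recovered, with 8 false calls, 4.91% of the calls made. In R7E against R7N at 9 weeks the shares were 55.2%, 83.6% and 100.0%, with 10 false calls, 5.92%. In R6 against WT they were 50.7%, 71.6% and 97.0%, with 4 false calls, 2.67%. The rod list, shifted in each simulation, was called in all 3 (adjusted p = 2.11e-27, 5.45e-33 and 6.37e-23), and of the lists not shifted 1 was called in R7E against R7N at 9 weeks and 0 in the other 2. Each probe set was simulated independently, so these list counts do not measure chance calls among correlated genes.

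Alternatives were quantile normalization, median centring, no lower limit, an offset in its place, no filter, a filter at the 60th percentile, no trend, no sex term, only the groups compared, a 1.5-fold minimum, a replicate block, and leaving out each array in turn. After the data were seen, fits without certain arrays were added: the 2 that stand apart from their groups, the 2 whose sex label the signals contradict, these 4 together, and the 4 highest in lens transcripts. The overlap of 3-week and 9-week calls was also counted without the first 2, with each age fitted alone, and with both changes. The groups compared share replicate numbers. The labels do not say that a number marks a shared animal, litter or day.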

Results

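Retinal RNA was compared between mouse lines that carry polyglutamine disease proteins and their controls. Expansion of the polyglutamine tract of ataxin-7 causes spinocerebellar ataxia type 7, in which the retina degenerates, and expansion of the tract of huntingtin causes Huntington disease. R7E mice carry mutant ataxin-7 and R7N mice normal ataxin-7, and each was sampled at 3 weeks (n = 5) and 9 weeks (n = 6). R6 mice carry mutant huntingtin and were sampled with WT mice of the same mixed strain at 9 weeks (n = 4 each). The deposited values are MAS5 signals of 22690 probe sets on 30 arrays, with a median signal per array of 39.3 to 48.3. Spearman correlations between pairs of arrays over the tested probe sets ran from 0.892 to 0.975. No pair of arrays shared more than 0.846% of its values.

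Transcripts of the sex chromosomes were set against the 11 female and 19 male labels. Xist, the transcript of the inactive X chromosome, had a signal of 1325 to 2270.5 in 9 of the labelled females and of 19.9 to 40.6 in the labelled males. The arrays labelled female as R7E_3w replicates 1 and 2 had Xist at 17.1 and 41.9, and the Y-linked gene Eif2s3y at 66.0 and 71.2, against 0.2 to 3.1 in the other labelled females. Their labels were kept as given, so the sex term holds 2 labels that these signals contradict. The Y-linked gene Uty was called higher in R7E than in R7N at 3 weeks, by 1.40, and stood at -0.06 without the sex term. R7N_3w replicate 1 and R7N_9w replicate 6 stood apart from their groups, with mean correlations to their own group of 0.925 and 0.926, against 0.943 to 0.967 in the other 28 arrays. The actin 3' to 5' ratio, a measure of RNA integrity, was 1.64 in the former and 0.975 to 1.19 in the arrays other than these 2. Each of these 2 is the only labelled female of its group, so the sex term draws in part on them. Lens transcripts were high on WT_9w replicate 4, R6_9w replicate 3 and R7N_9w replicates 6 and 9, where the crystallin Cryaa had signals of 4639.5, 3378, 2326 and 1183, against a median of 12.2 in the other 26 arrays.

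The first comparison asked what mutant ataxin-7 changed at the stage labelled onset. At 3 weeks Fabp7, a fatty acid binding protein of glial and progenitor cells, rose by 3.42 ± 0.44 on the log2 scale in R7E against R7N retinas, with a signal of 242 ± 31.5 against 20.04 ± 9.20 (n = 5 each), the latter under the filter's level of 26.9. Genes of the rod light response fell, among them Gnb1 (-0.94 ± 0.17 on the log2 scale) and Gngt1 (-0.80 ± 0.14), which encode subunits of transducin, the rod G protein. Dym, a gene of Golgi organisation, fell by 1.65 ± 0.15, and the water channel gene Aqp1 fell by 1.07 ± 0.15. In all, 198 of 13575 probe sets were called, 81 higher and 117 lower, for 171 genes, and 18 of them differed at least 2-fold.

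Further rises at 3 weeks were those of the aldo-keto reductase Akr1b8 (1.28 ± 0.24, adjusted p = 0.00375), Dcaf4 (1.18 ± 0.21), the cholecystokinin receptor Cckbr (1.14 ± 0.26) and the mitotic checkpoint kinase Bub1b (1.09 ± 0.21). The myelin gene Mbp rose by 0.92 ± 0.15 on its brightest probe set, while its other tested probe sets were not called, at -0.56 and 0.40. The lipid phosphatase gene Plpp2 fell by 1.17 ± 0.14 (adjusted p = 7.77e-06). Gulo (0.94), Selenbp1 (-1.24) and Ankrd33b (-0.97) were also called, but lost their calls without any of 2, 6 and 3 arrays left out singly. Fen1, a flap endonuclease, was called at -1.60, but its other probe set stood at 0.16, and any of 7 arrays left out singly ended the call. The genes of the transgene proteins were not called, with Atxn7 at 0.22 ± 0.32 and Htt at 0.09 ± 0.15. Whether these probe sets also detect the transgene transcripts is not given in the sources used here.

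Of the 18 rod phototransduction genes tested at 3 weeks, 5 fell and 0 rose, and 11 fell when adjusted over the list alone. The list median was -0.34 (adjusted p = 7.82e-10, and 0.0290 with an estimated correlation). The channel subunit gene Cnga1 fell by 0.48 ± 0.12. Another probe set was not called for Gnb1, at 0.52. Of 15 outer segment and cilium genes 3 fell (7 adjusted over the list alone), with a median of -0.23 (adjusted p = 4.66e-07, and 0.0162 with an estimated correlation). These were the retinol dehydrogenase Rdh12 (-0.79 ± 0.11), the disc rim protein Rom1 (-0.52 ± 0.12) and Tulp1 (-0.43 ± 0.11). Of 11 photoreceptor transcription factors 3 fell (4 adjusted over the list alone), namely Samd11 (-0.82 ± 0.16), Nrl (-0.55 ± 0.13) and Crx (-0.44 ± 0.10; another probe set not called, at -0.14), with a list adjusted p of 0.00249, and 0.0247 with an estimated correlation. Among 8 cone genes the cone transducin subunit Gnb3 rose by 0.69 ± 0.15, and the list was not called (adjusted p = 0.955).

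Inner retinal lists were lower as well at 3 weeks. Of 11 ganglion cell genes 4 fell (6 adjusted over the list alone), with a median of -0.30 (adjusted p = 8.80e-08, and 0.0160 with an estimated correlation). Among them were the neurofilament gene Nefm (-0.56 ± 0.12), the glutamate transporter Slc17a6 (-0.57 ± 0.13) and Thy1 (-0.45 ± 0.10). Of 12 bipolar cell genes 2 fell (4 adjusted over the list alone), Cabp5 (-0.55 ± 0.12) and Isl1, which is also in the ganglion list (-0.44 ± 0.11), with a list adjusted p of 0.00231, and 0.0160 with an estimated correlation. Amacrine genes had a median of -0.21 with 0 of 15 called (2 lower adjusted over the list alone; adjusted p = 0.00170, and 0.0162 with an estimated correlation). Other probe sets were not called for Slc17a6 (-0.031), Cabp5 (-0.34) or Isl1 (-0.18). R7N_3w replicate 1 was the highest array of its group for Cabp5, at 9.55 in log2 signal against 8.89 for the next. The lens list had a median of -1.76 with 0 of 8 genes called (adjusted p = 0.0254), a call lost with an estimated correlation (adjusted p = 0.487).

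Other lists called at 3 weeks were vascular cells (-0.20, adjusted p = 0.0261, and 0.0464 with an estimated correlation) and the SAGA complex with ataxin-7 partners (0.17, adjusted p = 0.0261, and 0.0390). In the SAGA list, a histone acetyltransferase complex that contains ataxin-7, 1 of 16 genes rose (2 adjusted over the list alone), Taf6l by 0.59 ± 0.14. Horizontal cells (-0.17, adjusted p = 0.0366), interferon response (0.28, adjusted p = 0.0332) and glycolysis (-0.11, adjusted p = 0.0150) were called with no member past the threshold. With an estimated correlation these became adjusted p = 0.0745, 0.146 and 0.235, and with fry 0.00900, 0.00883 and 0.120. Without R7N_3w replicate 1 the glycolysis (-0.056, adjusted p = 0.142), SAGA (0.12) and vascular lists (-0.10) were not called. Taf6l, Cyc1 and Isl1 lost their calls without any of 4, 6 and 4 arrays left out singly, and any of 4 arrays likewise ended the calls of the vascular, horizontal and interferon lists. Cyc1 was the 1 oxidative phosphorylation gene of 27 that rose (0.37 ± 0.09, list adjusted p = 0.596). Median, mean and test differed in sign for the cone, proteasome, clock, striatal and cholesterol lists, none of them called at this age.

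In 24 of the 31 calls named at 3 weeks every R7E array lay beyond every R7N array, but these genes were selected as called on the same arrays, so the 0.794% that chance gives an unselected gene is no benchmark. The count of 198 fell to 54 without R7N_3w replicate 1, to 114, 97 and 106 without R7E_3w replicates 3, 4 and 5, and to 42 when only the groups compared were fitted (1 higher and 5 lower if also without R7N_3w replicate 1), and 18 of the 31 calls ended without some single array. Without the 2 arrays that stood apart 178 were called, of which 75 were among the 198. Without R7N_3w replicate 1 the difference and adjusted p were -0.34 and 0.217 for Nrl, -0.34 and 0.155 for Crx, -0.41 and 0.141 for Rom1, -0.37 and 0.172 for Tulp1, -0.37 and 0.132 for Cabp5, -0.42 and 0.0817 for Thy1, -0.71 and 0.0764 for Samd11 and -0.53 and 0.0731 for Cnga1, without R7E_3w replicate 5 they were -0.49 and 0.106 for Slc17a6 and 1.12 and 0.0656 for Cckbr; any of 7, 5, 3, 3 and 3 single arrays ended the calls of Tulp1, Cnga1, Nrl, Crx and Rom1, and median centring gave 59 higher and 172 lower calls.

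At the stage labelled moderate, 9 weeks, the same comparison gave 1448 called probe sets, 762 higher and 686 lower, for 1111 genes, and 630 higher and 759 lower under median centring. Rod transcripts fell at this age too, with Gnb1 at 563 ± 187 in R7E against 1687 ± 140.0 in R7N (n = 6 each, -1.70 ± 0.15), though its other probe set was not called, at 0.53. Cabp4, a calcium sensor of the photoreceptor synapse, fell by 1.75 ± 0.15, and Reep6, a gene of rod membrane traffic, fell by 1.70 ± 0.13. Fabp7 rose by 3.84 ± 0.38, to 283 ± 28.9 against a low signal of 21.4 ± 11.0 in R7N (adjusted p = 1.20e-08). Of all calls 155 differed at least 2-fold, 33 higher and 122 lower.

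Other large rises at 9 weeks were those of Rgl3 (1.87 ± 0.31), Cckbr (1.63 ± 0.22), the desaturase Scd3 (1.54 ± 0.25), the calcium channel Itpr3 (1.49 ± 0.28), Alpk2 (1.44 ± 0.35) and the clathrin light chain Cltb (1.43 ± 0.15; 0.67 on another probe set). Nol12 rose by 2.01 ± 0.52, with R7N signals spread widely (19.6 ± 14.7). Large falls were those of the secreted protein Ccn4 (-1.91 ± 0.16), Aqp1 (-1.75 ± 0.13), Rabgef1 (-1.69 ± 0.13) and the chromatin protein Hmgb2 (-1.88 ± 0.25). Dym was lower in R7E than in R7N (-1.68 ± 0.13), but R7E lay near WT (-0.10 ± 0.15), and R7N above WT (1.58 ± 0.15). Edn2, an endothelin that photoreceptors release under stress, was lower in R7E than in R7N (-1.13 ± 0.28), with signals of 114 ± 22.6 and 261 ± 93.8, but R7E stood above WT (1.36 ± 0.31, adjusted p = 0.00300), which is of another strain. Atxn7 (-0.08 ± 0.28) and Htt (0.15 ± 0.13) were not called.

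Of 18 rod phototransduction genes 16 fell at 9 weeks (17 adjusted over the list alone), with a median of -0.79 (adjusted p = 2.73e-24, and 0.00232 with an estimated correlation). Examples besides Gnb1 were the cyclase activator Guca1b (-1.24 ± 0.12) and Cnga1 (-1.05 ± 0.10). Of 15 outer segment genes 9 fell, 9 of them also adjusted over the list alone (adjusted p = 1.69e-10, and 0.00406 with an estimated correlation), among them Rdh12 (-1.29 ± 0.10), Rom1 (-1.27 ± 0.10) and Prom1 (-0.68 ± 0.09). Photoreceptor transcription factors had 5 of 11 lower, by both adjustments, with Samd11 at -1.60 ± 0.14, Mef2c at -1.55 ± 0.19 and Nrl, which sets rod identity, at -1.11 ± 0.11 (list adjusted p = 0.00128, and 0.0281 with an estimated correlation). Cone genes moved both ways, with 3 of 8 higher and 3 lower by both adjustments, and the list was not called (adjusted p = 0.772). The cone transducin genes Gnat2 (0.99 ± 0.10) and Gnb3 (0.75 ± 0.13) rose, and the cone arrestin Arr3 fell (-0.45 ± 0.10; another probe set not called, at -0.43).

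Bipolar (1 of 12 lower, adjusted p = 0.0592) and amacrine lists (1 of 15 lower, adjusted p = 0.139), called at 3 weeks, were not called at 9 weeks. Their medians were -0.18 and -0.12, beside -0.20 and -0.21 at 3 weeks. With fry both lists were lower at 9 weeks too (adjusted p = 9.22e-05 and 0.0122), so the lost calls show no end of the fall. Ganglion cell genes were lower at 9 weeks, 6 of 11 (9 adjusted over the list alone), with Slc17a6 at -0.65 ± 0.11 and the synuclein Sncg at -0.44 ± 0.10 (list adjusted p = 2.60e-05, and 0.0367 with an estimated correlation). Oxidative phosphorylation genes were higher, 9 of 27 by both adjustments, among them Cox4i1 (0.40 ± 0.08), Uqcrc2 (0.37 ± 0.08) and Cyc1 (0.34 ± 0.08). That list was called (adjusted p = 3.37e-04), and not with an estimated correlation (adjusted p = 0.201). It was also lower in R7N than in WT, which is of another strain (median -0.09, adjusted p = 5.14e-05, and 0.157 with an estimated correlation). Cox4i1, for one, was at 1197 ± 152 in R7N, 1368 ± 76.5 in WT and 1592 ± 124 in R7E. Of 15 glycolysis genes 7 fell and 1 rose (7 and 2 adjusted over the list alone), with lactate dehydrogenase Ldha at -0.70 ± 0.12, hexokinase Hk2 at -0.67 ± 0.11 and Pfkp at -0.46 ± 0.07 (adjusted p = 8.21e-04, and 0.121 with an estimated correlation). Cholesterol synthesis had 2 of 13 lower by both adjustments (adjusted p = 0.0442, and 0.268 with an estimated correlation). With fry the oxidative phosphorylation, glycolysis and cholesterol lists were called (adjusted p = 0.00161, 3.23e-04 and 0.0114). Other probe sets were not called for Slc17a6 (-0.28), Uqcrc2 (-0.022) or Pfkp (-0.17), and Pfkp was also called higher in R7N than in WT. The lens list had a median of -2.04 with 0 of 8 called (adjusted p = 0.0491, and 0.571 with an estimated correlation); without R7N_9w replicate 6 it stood at -1.02 and was not called.

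Several lists were not called at 9 weeks although members were. Progenitor genes had 4 of 16 higher by both adjustments, among them the signal transducer Stat3 (0.73 ± 0.11), Six6 (0.50 ± 0.09) and Dll1 (0.56 ± 0.14), with a list adjusted p of 0.468. Other probe sets of Stat3 were not called, at -0.14 and 0.24. The medians of the progenitor and cone lists, and the mean of the heat shock list, differed in sign from their tests. Endoplasmic reticulum stress genes had 4 of 13 higher (5 higher and 1 lower adjusted over the list alone), with Pdia6 at 0.53 ± 0.10 and Xbp1 at 0.58 ± 0.12, of whose 3 other probe sets 1 was not called, at 0.35 (adjusted p = 0.328). Among lists tied to the disease proteins, neither was called: SAGA (0.258), in which the acetyltransferase Kat2b rose by 0.58 ± 0.09, and striatal signalling (0.362), in which 2 of 11 genes rose, among them Ppp1r1b (0.96 ± 0.20), and 1 fell (2 and 3 adjusted over the list alone). Adjusted p was 0.0754 for cell cycle with 1 of 8 lower, 0.368 for Muller glia with 2 of 14 higher, and 0.413 for immediate early genes with 1 of 9 lower. It was 0.915 for heat shock with 1 of 16 higher and 0.515 for apoptosis with 0 of 9 called. Gliosis (0.468), microglia (0.107), complement (0.468) and interferon (0.468) lists were not called either. With fry the cell cycle (adjusted p = 1.87e-04) and vascular lists (0.00136) were called lower. The SAGA (0.00174), microglia (0.0122) and progenitor lists (0.0254) were called higher by fry.

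All 43 calls named at 9 weeks held without any single array, and in 39 of them the ranges of the R7E and R7N arrays were apart, as selection of called genes on these arrays favours (0.216% by chance for an unselected gene). Without the 4 arrays highest in lens transcripts Nol12 and Edn2 were no longer called, and single arrays ended the calls of the cholesterol and lens lists (5 and 6 arrays).

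**Figure D1:**
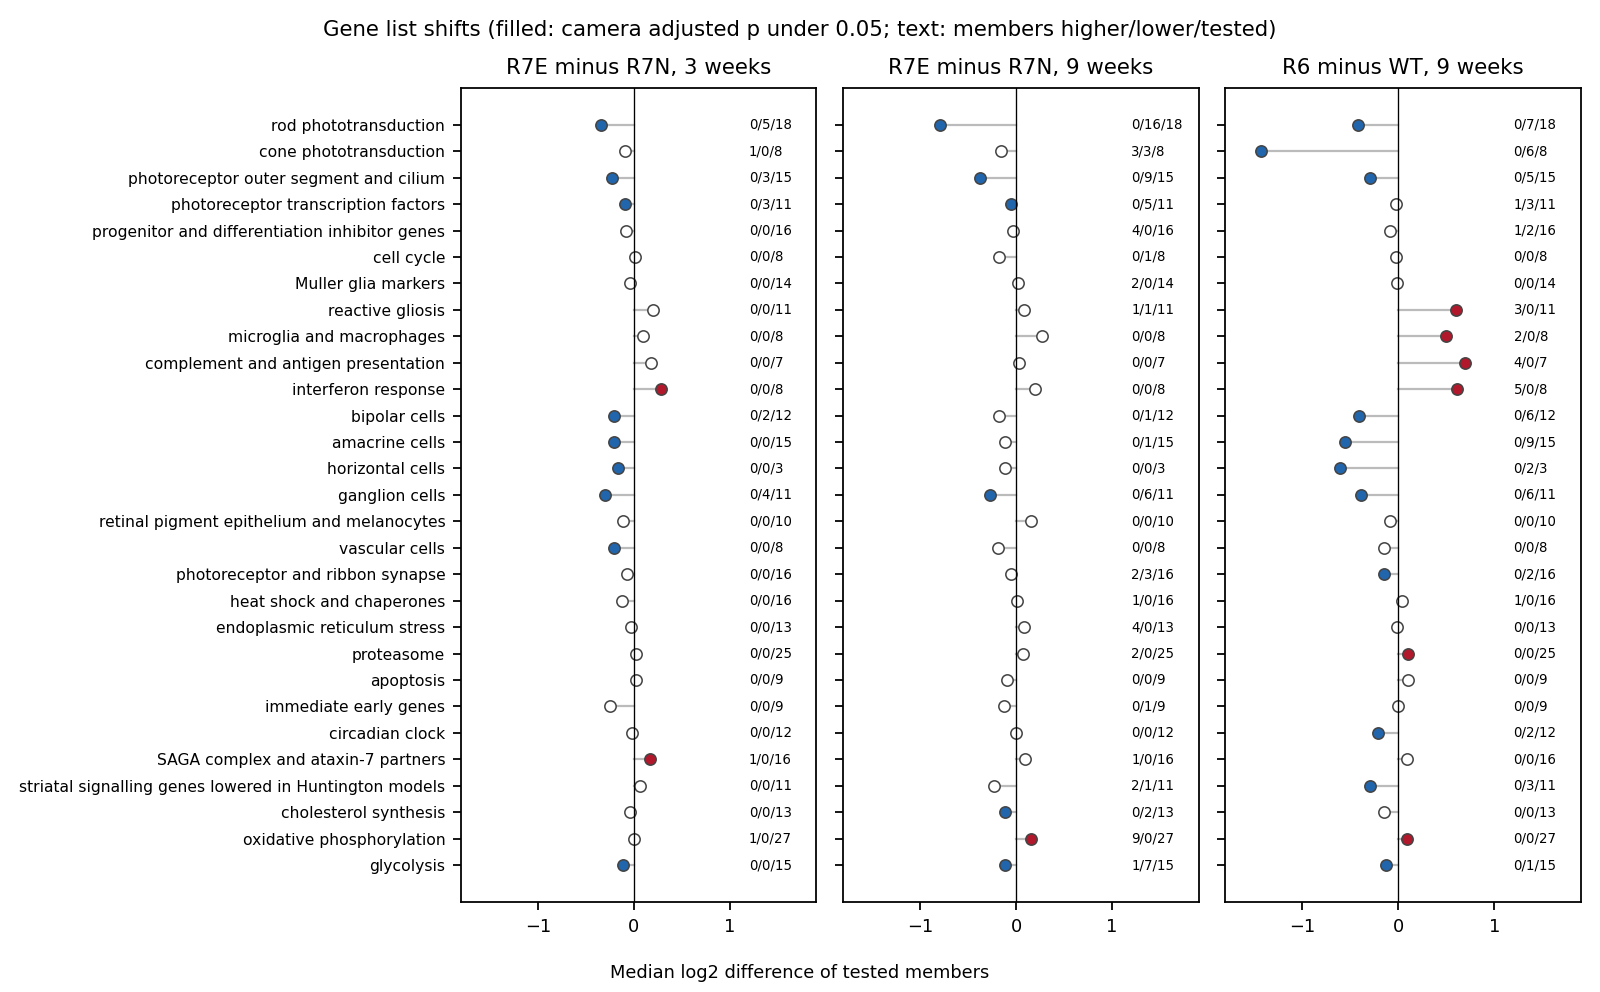
Median log2 difference of each gene list tested but lens (horizontal axis) in R7E against R7N at 3 weeks, R7E against R7N at 9 weeks and R6 against WT at 9 weeks, one panel per comparison, with filled points for lists at an adjusted p under 0.05 in camera and counts of higher, lower and tested genes beside each. The rod list lies at -0.34, -0.79 and -0.42, and the cone list at -0.09, -0.16 and -1.43.

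The change of the R7E effect between ages was tested as an interaction, on separate animals. Sgk1, a kinase gene, was at 398 ± 95.2 and 1250.3 ± 282 in R7N at 3 and 9 weeks and at 513 ± 98.7 and 449.5 ± 150.0 in R7E, a change of -1.96 ± 0.27. The collagen genes Col19a1 (-2.11 ± 0.36) and Col4a3 (-1.59 ± 0.24) and Hmgb2 (-1.65 ± 0.36) became lower with age in R7E relative to R7N. Medag (1.58 ± 0.29), Apobec2 (1.53 ± 0.28), the muscle glycogen phosphorylase Pygm (0.94 ± 0.17), Cltb (0.97 ± 0.22; another probe set not called, at 0.49) and Rtl8c (0.94 ± 0.13) became higher. The test called 142 probe sets, 42 higher and 100 lower. Atxn7 (-0.30) and Htt (0.07) were not called.

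Of 18 rod genes 3 became lower (12 adjusted over the list alone), and the list median changed by -0.42 (adjusted p = 1.19e-11), a call lost with an estimated correlation (adjusted p = 0.0914). Of the 81 rises at 3 weeks 47 were called higher again at 9 weeks, where independent calls would give 4.55, and 77 had the same sign. Of the 117 falls 76 were called lower again, where independent calls would give 5.91, 112 had the same sign and 1 was called higher. The ages share no array, but each R7N group holds 1 of the 2 arrays that stood apart, whose deviations correlated at 0.494, and the ages share a sex term, so independence is no full benchmark. In tests chosen after seeing the data, 34 of 47 rises and 82 of 131 falls were called again without these 2 arrays, where independent calls would give 2.62 and 7.43. With each age fitted alone it was 11 of 17 and 22 of 25 (0.726 and 1.01), and with both changes 1 of 1 and 1 of 5, too few to compare. The interaction count was 85 without the 2 arrays of contradicted sex label and 89 without the 4 arrays highest in lens transcripts. Edn2 (-1.68 ± 0.40) was called, and 9 arrays left out singly each ended that call.

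R6 retinas were compared with WT retinas of their own strain. The 3 largest falls were of cone genes. The cone opsin genes Opn1mw and Opn1sw were at 21.0 ± 19.1 and 56.2 ± 17.1 in R6 against 745 ± 93.8 and 1423 ± 198 in WT (n = 4 each), differences of -5.66 ± 0.33 and -4.70 ± 0.15, with another Opn1sw probe set at -2.06. Cone arrestin Arr3 fell by 3.30 ± 0.12 (-4.57 on another probe set) and the cone phosphodiesterase subunit Pde6h fell by 1.51 ± 0.15. The Opn1mw signal in R6 lay under the filter's level. Fabp7 rose by 2.69 ± 0.46, to 69.3 ± 31.2 against a low signal of 11.7 ± 5.84 in WT. There were 525 called probe sets, 170 higher and 355 lower, for 422 genes, and 71 of them differed at least 2-fold.

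Other large falls were those of the potassium channel subunit Kcne2 (-2.39 ± 0.17), Fndc1 (-1.61 ± 0.27), the plasma glutathione peroxidase Gpx3 (-1.62 ± 0.37) and opticin, Optc (-2.17 ± 0.44), with 2 of 4 R6 arrays at the lower limit. Rises included Akr1b8 (1.59 ± 0.25), the cholesterol exporter Abca1 (1.51 ± 0.18; 0.84 on another probe set), Alpk2 (1.45 ± 0.41) and Msrb2 (1.37 ± 0.32). Htt (0.33 ± 0.16) and Atxn7 (1.11 ± 0.33, adjusted p = 0.0527) were not called, though Atxn7 was past the threshold without WT_9w replicate 1 (0.0109) or replicate 3 (0.0450).

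All cone genes tested but Gnb3 and Cngb3 fell, 6 of 8 by both adjustments, with a median of -1.43 (adjusted p = 5.34e-25, and 7.85e-08 with an estimated correlation). Rod genes fell less, 7 of 18 (15 adjusted over the list alone), with a median of -0.42 and Gnb1 at -0.90 ± 0.18, its other probe set not called at -0.22 (adjusted p = 3.91e-14, and 0.00738 with an estimated correlation). Of 15 outer segment genes 5 fell (8 adjusted over the list alone), with Rdh12 at -0.85 ± 0.12 and Rom1 at -0.71 ± 0.12 (adjusted p = 2.05e-06, and 0.0132 with an estimated correlation). The transcription factor list was not called (adjusted p = 0.106), with 1 of 11 higher and 3 lower (2 and 4 adjusted over the list alone), while Samd11 fell by 1.09 ± 0.17 and Crx fell by 0.44 ± 0.10. Synapse genes had 2 of 16 lower (3 adjusted over the list alone; adjusted p = 0.00990, and 0.0252 with an estimated correlation).

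Inner retinal genes fell in R6 too. Of 15 amacrine genes 9 fell and 0 rose (9 and 1 adjusted over the list alone), with the calcium binding protein Calb2 at 614 ± 103 against 1486 ± 168 and the neuropeptides Vip at -1.15 ± 0.19 and Tac1 at -0.95 ± 0.17 (list median -0.56, adjusted p = 7.99e-10, and 3.56e-05 with an estimated correlation). Of 12 bipolar genes 6 fell (7 lower and 1 higher adjusted over the list alone), with Cabp5 at -0.81 ± 0.12 and Pcp2 at -0.73 ± 0.14 (adjusted p = 4.62e-05, and 9.27e-04 with an estimated correlation). Horizontal cells had 2 of 3 lower by both adjustments, Calb1 (-0.73 ± 0.09) and Septin4 (-0.61 ± 0.09), with adjusted p = 3.98e-06, and 4.77e-04 with an estimated correlation. Of 11 ganglion cell genes 6 fell (7 lower and 1 higher adjusted over the list alone), with Rbpms at -0.88 ± 0.17, Nefl at -0.53 ± 0.10 and Thy1 at -0.43 ± 0.10 (adjusted p = 1.37e-05, and 0.0166 with an estimated correlation).

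Striatal signalling genes, chosen for their fall in the striatum of Huntington models, were lower in the R6 retina as well, 3 of 11 (4 adjusted over the list alone): Penk (-1.17 ± 0.26), Rgs4 and the dopamine receptor Drd2 (-0.50 ± 0.12), with a list adjusted p of 4.29e-04, and 0.0326 with an estimated correlation. Clock genes had 2 of 12 lower (5 lower and 1 higher adjusted over the list alone), the clock output gene Dbp (-0.86 ± 0.11) and Per3 (-0.78 ± 0.19), with a list adjusted p of 0.00196, and 0.00794 with an estimated correlation. Other probe sets were not called for Septin4 (-0.22) or Per3 (-0.58), nor was 1 of those for Rbpms (-0.99). The time of day at which the retinas were taken is not given in the sources used here.

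Immune and glial genes rose in R6. Of 8 interferon response genes 5 rose by both adjustments, among them Ifit1 (1.37 ± 0.29) and Oasl2 (1.34 ± 0.25), with adjusted p = 1.39e-05, and 0.00483 with an estimated correlation. Complement and antigen presentation had 4 of 7 higher by both adjustments, among them the class I genes H2-K1 (1.22 ± 0.25; 1.02 and 0.62 on other probe sets) and B2m (1.13 ± 0.22) and the complement inhibitor Serping1 (0.76 ± 0.18), with adjusted p = 2.33e-04, and 0.0326 with an estimated correlation. Gliosis had 3 of 11 higher (4 adjusted over the list alone), with the glial filament Gfap at 1.11 ± 0.20, Stat3 at 0.89 ± 0.13 and A2m at 0.69 ± 0.19 (adjusted p = 1.72e-04, and 0.0717 with an estimated correlation). Microglia had 2 of 8 higher (4 adjusted over the list alone), Ctss (0.64 ± 0.15) and C1qb (0.78 ± 0.21), with adjusted p = 0.00139, and 0.0326 with an estimated correlation. Other probe sets were not called for C1qb (0.80) and, for 1 of 2, Stat3 (0.72). These 4 lists were also higher in R7N than in WT, and both comparisons use the same WT arrays.

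Small shifts were called for oxidative phosphorylation (0.09, adjusted p = 0.0160), the proteasome (0.10, adjusted p = 0.0287) and glycolysis (-0.12, adjusted p = 0.00609, with 1 of 15 lower). With an estimated correlation these became adjusted p = 0.337, 0.337 and 0.164, and 2, 4 and 1 arrays left out singly ended them. With fry the adjusted p values were 0.102, 0.0913 and 0.0223. The lens list was not called in R6, at a median of -1.60 (adjusted p = 0.0969), nor were Muller glia (0.772), pigment epithelium (0.631), vascular cells (0.435), heat shock (0.575) or apoptosis (0.550).

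In 42 of the 44 calls named for R6 the ranges of the R6 and WT arrays were apart, as selection of called genes on these arrays favours (2.86% by chance for an unselected gene), and the count of 525 fell to 310 without the 4 arrays highest in lens transcripts. Some single array ended each of 10 calls: Alpk2, A2m, C1qb, Serping1, Msrb2, Gpx3 and Drd2, which lost theirs without any of 2 to 7 arrays, Crx without R6_9w replicate 1 (-0.29), Thy1 without WT_9w replicate 2 (-0.34) and Per3 without R6_9w replicate 4 (-0.67).

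**Figure D2:**
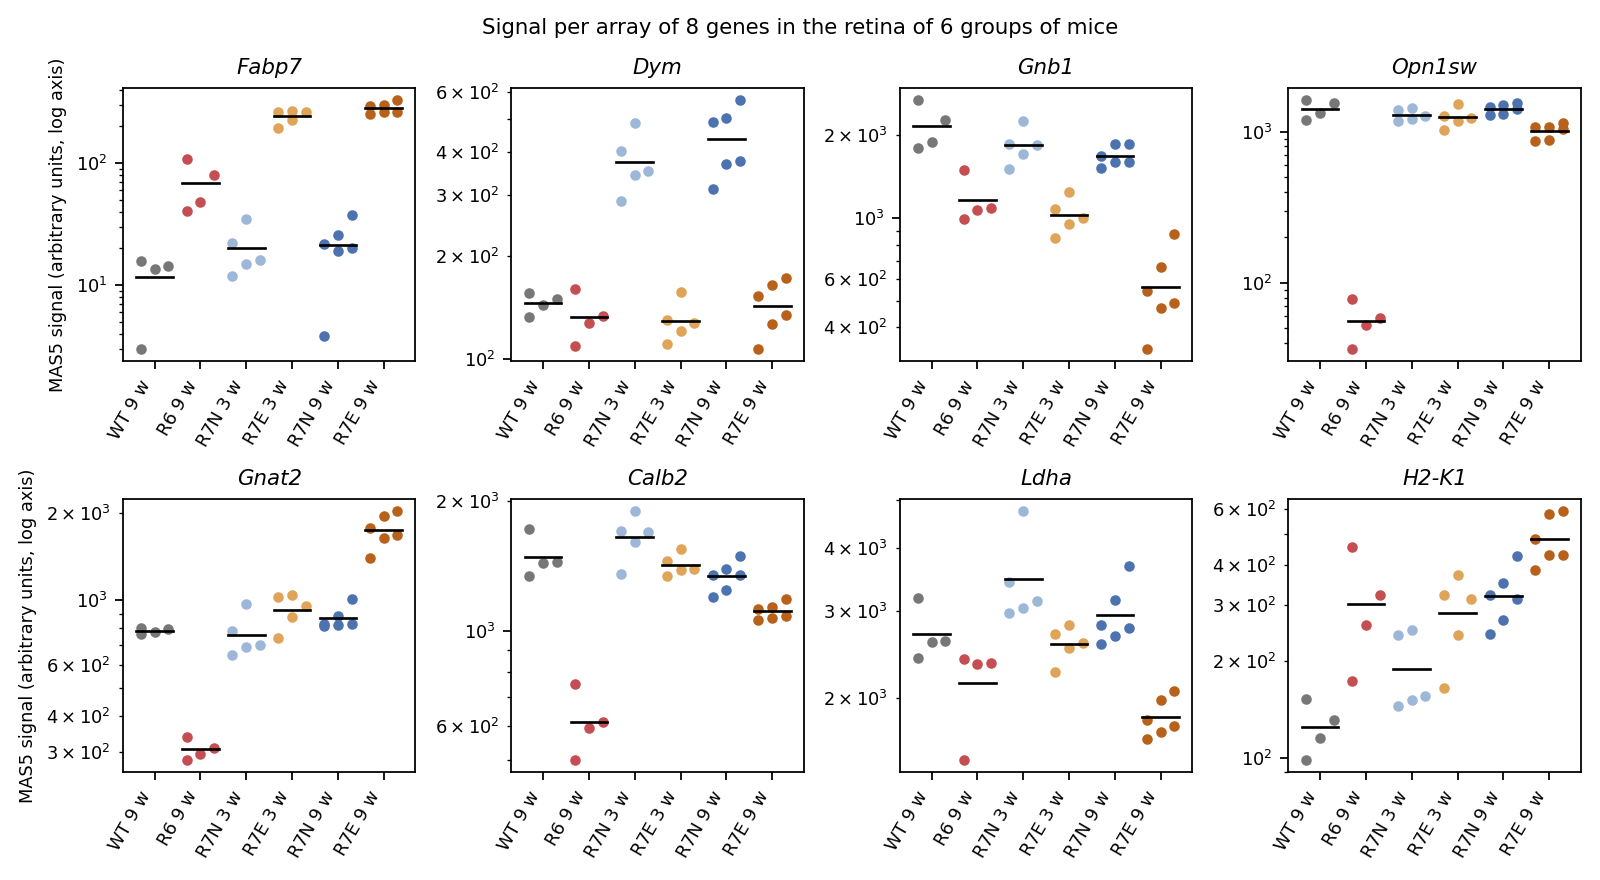
MAS5 signal (vertical log axis) of Fabp7, Dym, Gnb1, Opn1sw, Gnat2, Calb2, Ldha and H2-K1 on each of the 30 arrays, with 1 point per array in the 6 groups and a black line at the group mean. Fabp7 lay at 194.5 to 264.4 in R7E_3w replicates 1 and 2 and at 12.0 to 35.1 in R7N at 3 weeks.

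The R7E and R6 effects at 9 weeks were set against each other with no array shared. The difference of the effects was 5.25 ± 0.43 for Opn1mw, 4.24 ± 0.19 for Opn1sw, 2.86 ± 0.15 for Arr3 and 2.35 ± 0.15 for Gnat2, each lower in R6. The neuronal glycoprotein Olfm1 (1.95 ± 0.19) and Kcne2 (1.88 ± 0.22) were also higher in the R7E effect. Another probe set was not called for Opn1sw (1.13), nor was 1 of 2 for Olfm1. Dym (-1.53 ± 0.21), the linker histone H1f2 (-1.14 ± 0.20), Ahrr (-1.11 ± 0.21) and Edn2 (-1.72 ± 0.43) were lower in it, of which Dym (1.58) and Edn2 (2.49) were higher in R7N than in WT. There were 110 calls, 71 higher and 39 lower.

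Of 8 cone genes 6 differed (7 adjusted over the list alone), with a median difference of 1.93 (adjusted p = 1.47e-34, and 3.47e-09 with an estimated correlation). The amacrine (0.41, adjusted p = 1.23e-05, and 0.00171), horizontal (0.61, 8.08e-05 and 0.00199) and clock (0.13, 0.00839 and 0.0297) lists were higher in the R7E effect, and the interferon list lower (-0.42, 0.00105 and 0.0297), each pair without and with an estimated correlation. The rod list, lower in both lines, was lower in the R7E effect (-0.28, adjusted p = 1.71e-06), a call lost with an estimated correlation (adjusted p = 0.102).

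Calls were shared between the lines. At 9 weeks 67 probe sets were higher in both R7E and R6, where independent calls would give 9.54 (Fisher's exact test, p = 8.67e-40), and 162 were lower in both, where they would give 17.9 (p = 9.30e-118). Opposite calls were fewer than independent calls would give, 4 against 19.9 for higher in R7E and lower in R6, and 1 against 8.59 for the reverse. The comparisons share no array, but they share the residual variance and the sex term of 1 fit. Probe sets of 1 gene are not independent either, so independence is no full benchmark for these counts and p values. The count of 110 differences fell to 73 without the filter, to 73 without WT_9w replicate 4, to 67 without R7E_9w replicate 11 and to 34 without the 4 arrays highest in lens transcripts, and that of 229 shared calls fell to 136 without those 4. Edn2 was not called without any of 16 arrays left out singly.

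**Figure D3:**
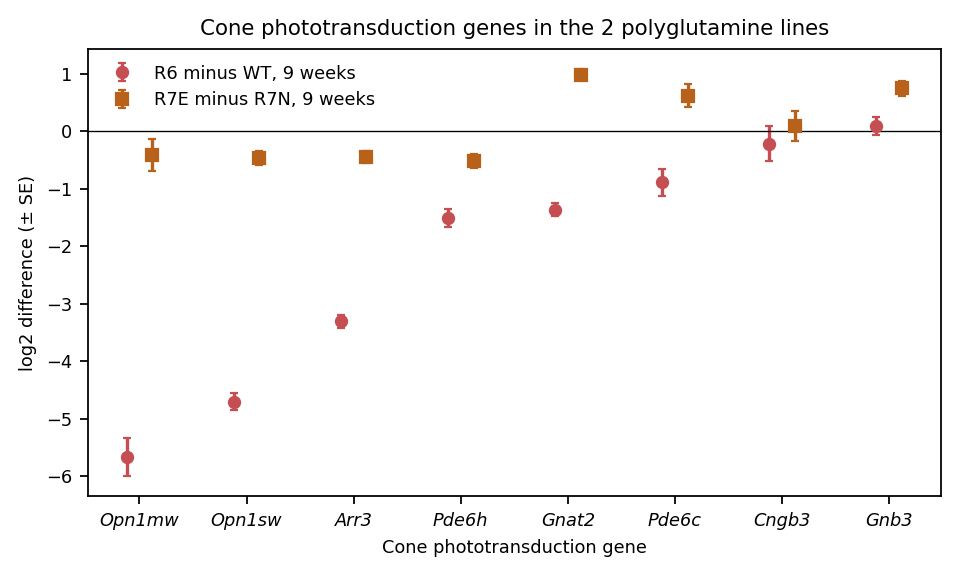
Log2 difference with 1 standard error (vertical axis) of the 8 tested cone genes (horizontal axis) in R6 against WT (n = 4 each) and in R7E against R7N at 9 weeks (n = 6 each). Opn1mw lies at -5.66 and -0.41, Gnat2 at -1.36 and 0.99, and Gnb3 at 0.10 and 0.75.

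Age was compared within each ataxin-7 line. From 3 to 9 weeks R7N retinas gained Edn2 (2.24 ± 0.28), the granzyme Gzmm (2.01 ± 0.15), Col19a1 (1.96 ± 0.25), Gpx3 (1.68 ± 0.32), Sgk1 (1.64 ± 0.19) and Hmgb2 (1.46 ± 0.25). Apobec2 (-1.97 ± 0.20), Selenbp1 (-1.40 ± 0.27), the matrix protein Sparc (-1.32 ± 0.11) and the deiodinase Dio2 (-1.12 ± 0.21) fell, though other Dio2 probe sets were not called, at 0.036 and -0.57. There were 567 calls, 282 higher and 285 lower, and 230 higher and 403 lower under median centring. Ganglion cell genes fell, 6 of 11 (7 adjusted over the list alone; adjusted p = 5.60e-09, and 0.00969 with an estimated correlation), and interferon genes had 1 of 8 higher (5 adjusted over the list alone; adjusted p = 0.00134, and 0.0230).

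In R7E 352 probe sets were called with age, 138 higher and 214 lower. Rod genes fell, 9 of 18 (11 adjusted over the list alone), with a median of -0.40 (adjusted p = 1.37e-15, and 0.0127 with an estimated correlation), and in R7N the rod list was not called (adjusted p = 0.938), though the test of the difference between the lines lost its call with an estimated correlation (adjusted p = 0.0914). Ganglion cell genes fell in R7E too, 6 of 11 (9 adjusted over the list alone; adjusted p = 5.16e-10, and 0.00636). Pigment epithelium genes rose, 4 of 10 by both adjustments, among them the opsin Rgr (1.24 ± 0.26), with adjusted p = 1.72e-04, and 0.0433 with an estimated correlation. In R7N 1 of 10 rose and that list was not called (median 0.13, adjusted p = 0.280). Rgr signals in R7N were also higher at 9 weeks, 113.8 ± 43.6 against 52.3 ± 11.6, so its rise is not particular to R7E. Medag (1.28 ± 0.21), Fen1 (1.62 ± 0.38), Msrb2 (1.19 ± 0.28) and Rgl3 (1.18 ± 0.32) rose, and Ccn4 (-1.28 ± 0.16), Selenbp1 (-1.10 ± 0.28) and the stress gene Gadd45a (-1.04 ± 0.22) fell. Other probe sets were not called for Fen1 (0.13) or Selenbp1 (-0.27). The count was 214 without R7E_3w replicate 2 or without replicate 5, 143 without both arrays of contradicted sex label and 596 without the 2 arrays that stood apart. The calls of Fen1 (without R7E_3w replicate 5, 1.23), Rgr (likewise, 0.98), Msrb2, Rgl3 and Selenbp1 ended without 1 or more single arrays.

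R7N and WT retinas at 9 weeks differ in the ataxin-7 transgene and in strain together, so no difference between them can be assigned to either from this comparison alone. Edn2 was 5.61-fold higher in R7N, at 261 ± 93.8 (n = 6) against 45.1 ± 12.5 (n = 4), and Dym was 2.99-fold higher, at 438 ± 98.1 against 145 ± 9.96. Atxn7 (1.59 ± 0.30), the class I genes H2-K1 (1.36 ± 0.22; 0.63 and 1.01 on other probe sets) and H2-D1 (1.15 ± 0.18) and the collagen processing gene Pcolce (1.42 ± 0.25) were also higher. The retinoic acid binding protein Crabp1 (-1.81 ± 0.23), Srrm2 (-0.94 ± 0.18) and Fgf1 (-0.55 ± 0.12; another probe set not called, at -0.30) were lower, and Htt (0.19 ± 0.15) was not called.

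Glial and immune lists were higher in R7N than in WT. Gliosis had 3 of 11 higher (6 adjusted over the list alone; median 0.65, adjusted p = 6.05e-11, and 0.00663 with an estimated correlation). Complement and antigen presentation had 4 of 7 by both adjustments (median 0.97, adjusted p = 2.90e-10, and 0.00469). Microglia had 1 of 8 (4 adjusted over the list alone; adjusted p = 2.49e-05, and 0.0113), and interferon response 1 of 8 (4 adjusted over the list alone; adjusted p = 7.01e-06, and 0.00642). The comparison called 57 probe sets, 41 higher and 16 lower, and without the 2 arrays that stood apart 80, 41 higher and 39 lower. The count of 57 became 29, 34 and 33 without WT_9w replicate 3, WT_9w replicate 4 and R7N_9w replicate 11, 27 with only these groups fitted and 30 without the 4 arrays highest in lens transcripts. Srrm2 was not called without WT_9w replicate 4 (-0.75), nor Fgf1 without any of 7 arrays left out singly.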

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

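Of the tests here, those on the Dym line and probe set, the arrays that stood apart and the cone genes were chosen after the results were seen, except that on lens level and female sex. The tests on Dym's neighbours, the 3-week calls and the splits were written before their results.

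The first pattern was Dym, lower in R7E than in R7N at both ages. A fault of 1 probe set was argued against by the other Dym probe set, at -1.32 at 9 weeks and -1.04 at 3 weeks, and a change of its chromosomal region by its 20 nearest tested genes on chromosome 18, of which 1 was lower in R7E (5% against 5.73% of 8044 genes). Dym in R7E stood -0.10 (SE 0.15) from WT at 9 weeks while R7N stood above WT, so the Dym difference may belong to the R7N line, a hypothesis found and tested on the same data. The 198 calls at 3 weeks as a set went otherwise, with a median of 0.51 in their own direction in R7E against WT at 9 weeks, beside 0.57 at 3 weeks and 0.02 for R7N against WT. Of them 183 had the same direction and 3 were called opposite in R7N against WT, Dym on 2 probe sets and Mab21l1, while strain stays open since WT is of another strain.

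The next pattern was R7N_3w replicate 1 and R7N_9w replicate 6, whose deviations from their groups correlated at 0.494 over 13195 probe sets. A first reading, that lens tissue was carried in, rested on 4 of 8 lens genes being highest of their group in both arrays and stays open. Female sex stays open for the lens level too: 4 of 7 other labelled females, all R7E, stood above every male of their group, but R7N_3w replicate 1 (7.24) lay below the male replicate 2 (7.29) and 3 of the 4 arrays highest in lens transcripts are labelled male. As causes of the deviations, lens tissue was argued against by a highest correlation of 0.0941 with 2 lens-rich arrays, and female sex by a median correlation of 0.0158 over 7 other females (-0.02 to 0.25). Degraded RNA may account for R7N_3w replicate 1, with an actin ratio of 1.64 against 0.975 to 1.19 elsewhere, and stays open for R7N_9w replicate 6, at 1.19, where the bound was loosened after its value was seen.

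The last pattern was the fall of cone genes in R6. The 8 genes had a spread of 5.76, beyond their standard errors, from -5.66 for Opn1mw, whose R6 signal lay under the filter's level, over -3.30 for Arr3 and -0.89 for Pde6c to 0.10 for Gnb3, which with Cngb3 was not called. RNA of the whole retina does not show whether each listed transcript, Gnb3 among them, came from cones alone. Fewer cones with equal loss of each transcript stays open all the same, since 2 probe sets of 1 gene also differed (Opn1sw -4.70 and -2.06, Arr3 -3.30 and -4.57), and the variance between genes was 3.34 times that between probe sets of a gene (exact permutation test over all pairings of the 11 probe sets, p = 0.177). A general loss of photoreceptor transcripts was argued against by the rod median of -0.42 beside the cone median of -1.43, and a larger share of amacrine or bipolar cells by their medians of -0.56 and -0.41. A larger share of glial or immune cells was not tested. The gliosis, microglia, complement and interferon lists rose in R6, while the Muller glia list was not called. Lower transcription within cones, with or without their loss, may remain as a hypothesis, which was not tested.

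Dixon's test was applied to 450 sets of values of 1 group, where chance alone would give 22.5, and found 33, 15 on quality or list means and 18 on genes. Far from their group (nearest other in parentheses) were the median signal of R6_9w replicate 4 at 47.9 (42.9) and R7N_9w replicate 10 at 48.3 (44.5), and the mean correlation of R7E_9w replicate 11 at 0.955 (0.964). R7N_3w replicate 1 stood out in mean correlation at 0.925 (0.948) and actin ratio at 1.64 (1.13). In list means on the log2 scale these were rod genes in R7N_9w replicate 6 at 10.21 (10.45), outer segment genes in R7E_3w replicate 3 at 9.45 (9.95), photoreceptor transcription factors in R7N_3w replicate 5 at 8.85 (8.81) and Muller glia in R7E_9w replicate 9 at 8.61 (8.69). Gliosis stood out in WT_9w replicate 4 at 6.47 (5.97) and R7N_3w replicate 4 at 6.74 (6.36), ganglion cells in R7E_3w replicate 5 at 8.00 (8.09) and pigment epithelium in WT_9w replicate 1 at 6.29 (5.97). Lens stood out in R6_9w replicate 3 at 10.27 (4.33) and glycolysis in WT_9w replicate 2 at 10.46 (10.32).

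For single genes, in log2 signal, Fabp7 was low in WT_9w replicate 4 at 1.68 (3.78). In R7N_9w replicate 10 Fabp7 was at 1.93 (4.24), Alpk2 at 2.38 (4.72), Ccn4 at 7.45 (7.72) and Pdia6 at 7.17 (7.39). Samd11 stood out in R6_9w replicate 1 at 8.96 (9.22), R7N_3w replicate 2 at 9.72 (10.35) and R7E_9w replicate 10 at 9.09 (8.44). In R7E_9w replicate 10 Reep6 was at 10.57 (9.90) and Ppp1r1b at 5.40 (5.98). Cnga1 was at 10.33 (10.47) in R7N_9w replicate 6, Rdh12 at 10.65 (10.83) in R7N_3w replicate 2, Cabp5 at 9.55 (8.89) in R7N_3w replicate 1, Slc17a6 at 6.61 (7.04) in R7E_3w replicate 5 and Atxn7 at 5.46 (5.87) in R7E_3w replicate 1. Pde6h was at 9.49 (9.28) and Gfap at 5.35 (5.77) in WT_9w replicate 2, and Nefl was at 9.59 (9.86) in R6_9w replicate 3.

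By the test of the difference itself, 142 probe sets changed in the R7E effect with age. The named ones were Medag (1.58), Apobec2 (1.53), Cltb (0.97), Pygm (0.94), Rtl8c (0.94), Col19a1 (-2.11), Sgk1 (-1.96), Edn2 (-1.68), Hmgb2 (-1.65) and Col4a3 (-1.59). Between the R7E and R6 effects 110 differed, the named ones being Opn1mw (5.25), Opn1sw (4.24), Arr3 (2.86), Gnat2 (2.35), Olfm1 (1.95), Kcne2 (1.88), Edn2 (-1.72), Dym (-1.53), H1f2 (-1.14) and Ahrr (-1.11).

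Calls were counted again over other splits of the same arrays, 100 with the real one included, or 35 for R6 against WT. In 1 of 100, the real one, the count was reached for R7E against R7N at 3 weeks (198, highest other 6) and 9 weeks (1448, highest other 431), the change with age (142, highest other 43), age in R7N (567, highest other 211) and in R7E (352, highest other 245), R7N against WT (57, highest other 6) and the shared calls (229, highest other 0). In 1 of 35 it was reached for R6 against WT (525, highest other 6). Chance was thus made unlikely for these except the shared calls. It was not excluded, since the shares can go no lower and were not adjusted over the comparisons. Shuffling within each comparison takes away the effect of each line, so few calls could be shared, and the overlap itself was not tested by it. For the difference of the R7E and R6 effects 2 of 100 splits reached 110, the real one and another that gave 280. That shuffle mixed arrays of different strains, so it cannot exclude chance, and what sets the other split apart was not tested. For lists, 1 of 100 splits reached the 12 called at 3 weeks (highest other 10), 1 of 35 the 17 in R6 (highest other 16) and 5 of 100 the 8 called at 9 weeks (highest other 10). Chance stays open for the last, and other splits came close to the counts at 3 weeks and in R6. The other splits called a median of 3 lists at 3 weeks, 4.5 in R6 and 3 at 9 weeks.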

How the results depend on the processing

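Fits without certain arrays other than 1 at a time were chosen after seeing the data; the other alternatives were planned. Of 180 gene results and 81 list results, no list reversed under any alternative, and where a call or count moved the cause was not tested unless fewer arrays or a stricter threshold shows it. Without the lower limit, or with an offset in its place, 180 of 180 gene results were the same. Signal over background limits dim genes, for which no detection calls were used.

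No filter gave 73 calls for the R7E minus R6 difference. Fitting only the groups compared gave 42 for R7E against R7N at 3 weeks and 27 for R7N against WT. A 1.5-fold minimum left 95 calls at 3 weeks, 547 at 9 weeks, 301 in R6 against WT, 193 for age in R7N, 154 for age in R7E and 104 shared calls. Without the 2 arrays that stood apart, age in R7E gave 596. Without the 2 of contradicted sex label the change with age gave 85 and age in R7E 143. Without the 4 highest in lens transcripts the counts were 89 for the change with age, 310 for R6 against WT, 34 for the R7E minus R6 difference, 30 for R7N against WT and 136 shared.

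The replicate number as a replicate block gave 30 calls at 3 weeks and 64 for the R7E minus R6 difference. Same-numbered arrays deviated together at -0.12 to 0.33, and 1 of 5, 1 of 6 and 0 of 4 pairs correlated best with their own number, so the numbers were not taken as pairs. Htt at 3 weeks then stood at -0.070 and Atxn7 at 9 weeks at 0.063.

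Directions that turned were of genes not called, but for Uty. Without the sex term Uty at 3 weeks was -0.064 and Htt -0.042. Htt at 3 weeks was -0.092 without the apart arrays, -0.018 without those of contradicted sex and -0.17 without all 4. Atxn7 at 9 weeks was 0.041 with only the groups compared. Leaving out single arrays, Htt ran from -0.029 to 0.29 at 3 weeks and from -0.10 to 0.16 in the change with age, and Atxn7 from -0.18 to 0.033 at 9 weeks.

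Leaving out single arrays gave 54 to 197 calls at 3 weeks, 67 to 141 for the R7E minus R6 difference, 29 to 49 for R7N against WT and 214 to 380 for age in R7E, lowest without R7N_3w replicate 1, R7E_9w replicate 11, WT_9w replicate 3 and R7E_3w replicate 2. It gave 1102 to 1413 calls at 9 weeks, 365 to 459 for R6, 115 to 183 for the change with age and 404 to 538 for age in R7N. Of 2084 such gene results 144 lost their call, and of 969 list results 82. Among genes, calls were lost by 28 with a 1.5-fold minimum, 32 with only the groups compared, 19 without the lens-rich arrays, 17 without a filter, 14 without the apart arrays, 11 without those of contradicted sex, 17 without all 4, 8 without the sex term, 5 with quantile normalization, 5 without a trend and 1 with median centring. With the replicate block it was 29 of 148, and 2 reversed. Among lists, 16 were lost without the apart arrays, 16 without all 4, 13 with quantile normalization, 11 of 76 with the 60th percentile filter, 10 without the lens-rich arrays, 8 without those of contradicted sex, 6 with only the groups compared, 5 without the sex term, 4 without a filter, 3 with median centring, 1 without the lower limit and 3 of 52 with the replicate block.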

Other observations

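The comparisons of R7E with WT and of R6 with R7N, and all values given here, were chosen after the data were seen. Immune and glial genes, not called as lists by camera between R7E and R7N at 9 weeks, were higher in R7E than in WT. Gliosis had 6 of 11 genes higher with a median of 1.01 (adjusted p = 5.97e-06, and 0.0419 with an estimated correlation). Microglia had 5 of 8 (0.76, adjusted p = 2.87e-05, and 0.0188), complement and antigen presentation 4 of 7 (1.12, 2.87e-05 and 0.0254) and interferon response 5 of 8 (0.58, 9.62e-04 and 0.0254). Single genes were H2-K1 (1.96), B2m (1.12), Stat3 (1.06) and Gfap (1.01). Between R6 and R7N none of these lists was called (adjusted p = 0.405, 0.936, 0.334 and 0.249), and of these genes Stat3 was called (0.56), with Gfap at 0.37, B2m at 0.16 and H2-K1 at -0.15. R7E and WT differ in strain as well as in the transgene, as do R6 and R7N, and both R7E and R7N were set against the same WT arrays.

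With age R7N retinas also had higher complement (0.44, adjusted p = 0.00134, and 0.0776 with an estimated correlation) and cell cycle lists (0.15, 0.00843 and 0.0230), and lower horizontal (-0.46, 0.00134 and 0.0153), amacrine (-0.19, 0.00477 and 0.0230) and progenitor lists (-0.19, 0.00477 and 0.0173). In R7E outer segment genes were lower with age (-0.16, adjusted p = 4.32e-06, and 0.0403 with an estimated correlation). Further lists were called with age, each losing its call with an estimated correlation (median, then adjusted p without and with it). In R7N these were endoplasmic reticulum stress (-0.16, 0.0156 and 0.184) and oxidative phosphorylation (-0.08, 0.00836 and 0.442). In R7E they were complement (0.34, 4.81e-04 and 0.0715), interferon (0.23, 0.0299 and 0.134), gliosis (0.33, 0.0425 and 0.351), microglia (0.28, 0.0445 and 0.216), photoreceptor transcription factors (-0.14, 0.0445 and 0.134) and horizontal cells (-0.25, 0.0299 and 0.0715), of which interferon, gliosis, microglia, transcription factors and horizontal cells were not called without any of 3, 4, 7, 5 and 1 single arrays.

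Other comparisons also held lists called only at the preset correlation, given in the same way. For the change of the R7E effect with age these were outer segment (-0.22, 0.00312 and 0.194), Muller glia (0.14, 0.0258 and 0.183) and oxidative phosphorylation (0.09, 0.00312 and 0.366). Without R7N_3w replicate 2 the Muller glia list stood at 0.067 and was not called. For the R7E minus R6 difference they were outer segment (-0.16, 0.00819 and 0.173), photoreceptor transcription factors (-0.14, 0.00819 and 0.0544), gliosis (-0.21, 0.00819 and 0.219), complement (-0.33, 0.00819 and 0.153) and striatal signalling (0.21, 0.0315 and 0.194). For R7N against WT they were rod (-0.18, 4.49e-04 and 0.239), cone (0.20, 0.00797 and 0.0722), cell cycle (0.12, 0.0454 and 0.0920), horizontal cells (-0.23, 0.0454 and 0.0983), pigment epithelium (0.25, 0.0153 and 0.169) and oxidative phosphorylation (-0.09, 5.14e-05 and 0.157). Without WT_9w replicate 1 the horizontal (-0.063) and cell cycle lists (0.075) were not called, nor was pigment epithelium (0.22) without WT_9w replicate 3.

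The arrays of contradicted sex label, R7E_3w replicates 1 and 2, had Dym at 129.9 and 156.9, beside 110.2 to 127.1 in the other R7E arrays of 3 weeks and 287.7 to 488.4 in R7N. Their Fabp7 signals were 264.4 and 194.5, beside 225.5 to 265.6 and 12.0 to 35.1.

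R7N_3w replicate 1 and R7N_9w replicate 6 had 1 Ehmt2 probe set at 4.6 and 2.5, against means of 78.1 and 76.7 in the rest of their groups, and the other at 260.3 and 319.9, against 439.95 and 394.7. Of 4 Fscn1 probe sets 2 were lower in both arrays, at 6.2 and 6.5 against 95.7 and 73.9 and at 67.7 and 90.4 against 197 and 160.3. The other 2 were lower in the former and higher in the latter, at 313 and 274 against 336 and 219.7 and at 204.7 and 243 against 234 and 202. Ehmt2 and Fscn1 were picked after their values were seen.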
